A study of Mus musculus with 6 samples.

How the data were processed

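RNA was extracted from isolated duodenal crypts of mice with a silica-column kit (RNeasy Mini Kit), and libraries were prepared from polyadenylated RNA by a sequencing company, per the labels' protocols. There were 3 libraries from mice heterozygous for the Hnf1a-MODY mutation in glucagon-producing cells (HTZ) and 3 from wild-type mice (WT), each with 2 males and 1 female, grouped by the genotype, sex and number in the titles. The HTZ female carries the number 2 in its title but 1 in the name of its deposited table, and the title was followed; which number is right is not known. Both the labels and the files say nothing further on litter, collection day or sequencing batch, and the labels do not state that each library came from a different animal.

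The authors deposited 1 table per library with 48709 genes. Per the file headers, each table holds counts of exon, exon-exon and intron reads, both unique and total, together with TPM and RPKM values. The deposited counts are raw whole numbers, and the column headed as the expression value equals the total exon reads in every gene of every library. The deposited TPM values have the same sum in each library, and the deposited RPKM values divide the exon count by exon length and by 1 number per library that is larger than the sum of the gene reads; both were read to learn the units and were not tested. The genome build was mm10 per the submitters' processing notes, and the aligner, the counting tool, their versions and the use of strand are not given in the sources used here. Of the gene identifiers 48349 were found in the GENCODE M21 annotation of the same assembly, all on the same chromosome and 88.4% with the same start and end, so coordinates are printed as in the deposited tables or that annotation. Because the use of strand is not stated, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies were treated as uncertain; between 2.32% and 2.64% of exon reads were placed in more than 1 gene.

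All tests of genes used the deposited counts of total exon reads. Exon counts per library were between 29675588 and 35822325. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), which kept 13864 genes, and library sizes were scaled by TMM. Genotype was tested with edgeR's quasi-likelihood fit and test (robust, R 4.3.3, edgeR 4.0.16) in a model with sex and genotype on all 6 libraries, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The fit had 3 residual degrees of freedom, and the common biological coefficient of variation was 16.2%. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The sex coefficient of the same fit compared females with males, and a model with the sex-by-genotype interaction compared the genotype difference between the sexes, with 1 female per genotype and the spread taken from the males. Levels are CPM on TMM-scaled library sizes, except Xist and Y-linked genes in the sex check, which are on library totals.

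Before the data were examined, 49 gene lists were fixed from general knowledge of the gut, covering epithelial cell types and states, regional identity, HNF1A targets, nutrient metabolism, signalling, immune and stress responses, and cell types that a crypt preparation could carry along. The 46 lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 46 lists. Beside it stand the same test with an estimated correlation, limma's fry, and counts of genes adjusted over the list alone. Fibroblast, adipocyte and mesentery, and erythroid lists had 4, 4 and 3 members above the filter and were not tested. Gene symbols were matched to the deposited names or through gene identifiers, and 6 of 1196 entries had no match. Shares of counts were compared by an exact two-sided permutation test over the 20 assignments of 3 libraries against 3, adjusted over 6 measures. Windows of 10 Mb were tested for called genes by Fisher's exact test with Benjamini-Hochberg adjustment over 256 windows, and genes within 10 or 5 Mb of Hnf1a and of Gcg by camera, adjusted over these 4 tests.

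The genes named in the text followed a rule fixed before the data were examined. Hnf1a, Hnf1b, Gcg, Chga and Neurog3 were always named. Among called genes at a mean of at least 1 CPM, with a gene symbol other than a clone, predicted gene or pseudogene name and with all 3 HTZ libraries on 1 side of all 3 WT libraries, the 10 largest rises and the 10 largest falls were named. For each called list the 3 members with the smallest p and the most abundant one could be named, and for other lists the member with the smallest p and the most abundant one; where lists overlap or are given in 1 sentence, not all of these are printed. Which of them to print was decided after their values were seen. For sex, Xist and the Y-linked genes were named, and for the interaction the 5 genes with the smallest adjusted p. Lct, Slc5a1 and Gzma are printed beside the lists that hold them. Kdm6a, Eif2s3x, Kdm5c, the clock genes Dbp and Arntl and the genes H2-Q2 and H2-D1 were named after their values were seen.

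The script was tested on simulated counts drawn from the real libraries' means, with 200 of 13712 genes changed. For the genotype comparison it called 130 of the 200 changed genes and 20 others, recovering 23.9%, 73.1% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, and with nothing changed it called 9 genes. For the interaction it recovered 0%, 13.4% and 71.2% at these sizes over 13726 genes. In the list test the 1 changed list was called, with 1 false call among 45 lists, where lists sharing genes with the changed one were not counted as false. Simulated genes varied independently of each other, so false calls in lists whose genes vary together were not measured.

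Alternatives fixed before the data were examined were no low-count filter and one at 50 counts, median-of-ratios and upper-quartile factors, DESeq2 (1.42.0), limma-voom, a non-robust fit, no sex term, a replicate block (male 1, male 2 and the females, whose numbers differ, each paired across genotypes), protein-coding genes only, removal of mitochondrially encoded genes and of the 10 largest genes, males only, and each library left out in turn. Chosen after the data were seen were unique exon reads, a term for the division of the libraries by intron share (in place of sex or beside it), each side of that division alone, libraries left out without a sex term or with DESeq2, and removal of the enterocyte, lipid absorption and lymphocyte lists.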

Results

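Bulk RNA sequencing was carried out on crypts isolated from the mouse duodenum, the epithelial glands that hold the intestinal stem cells, dividing progenitors, Paneth cells and young secretory and absorptive cells. The mice were heterozygous (HTZ) for an Hnf1a mutation directed to glucagon-producing cells with a Cre line, or were wild-type (WT) controls. Titles of both genotypes carry the same Glu-Cre Hnf1a-MODY name, and they do not state whether the WT mice carry the Cre. The mutation is modelled on HNF1A-MODY, an inherited diabetes caused by mutation of the transcription factor HNF1A, and the study asked how it affects gene expression, morphology and function of the intestine. There were 3 libraries per genotype, 2 from males and 1 from a female. The labels name them by genotype, sex and number without saying more on the animals, so p-values measure the spread between these libraries. Exon counts per library were 33261003 for HTZ male 1, 33416467 for HTZ male 2, 29675588 for HTZ female 2, 31955029 for WT male 1, 33970641 for WT male 2 and 35822325 for WT female 1. After removal of genes with low counts, 13864 genes were tested. Levels below are CPM (exon counts relative to the TMM-scaled library size) as mean ± SD of the 3 libraries of a genotype, and changes are log2 fold changes of HTZ over WT. Reads in introns made up 11.6%, 11.5% and 11.3% of gene reads in WT male 1, WT male 2 and HTZ female 2, and 9.61%, 9.22% and 9.14% in HTZ male 1, WT female 1 and HTZ male 2. This division cut across genotype through the females only, as both HTZ males lay on the lower side and both WT males on the higher side. With the males alone, genotype and intron share therefore cannot be told apart. List medians within each side of the division are given beside the pooled ones. The lower side sets 2 HTZ males against 1 WT female and the higher side 1 HTZ female against 2 WT males. Differences within a side therefore mix genotype with sex and rest on 1 library in 1 genotype, which is assumed to vary like the others.

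The targeted gene and the gene that marks the targeted cells were compared first. Hnf1a (ENSMUSG00000029556, chromosome 5, 114948980 to 114971094, minus strand, mm10) was at 45.2 ± 3.91 CPM in WT and 42.9 ± 3.17 CPM in HTZ crypts (SD, n = 3 each). Its log2 fold change of -0.07 (SE 0.09) was within the spread between libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.66). HNF1A is made in most epithelial cells of the gut, so whole-crypt counts measure mainly cells outside the targeted population and do not check the genotype labels. Gcg (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650, minus strand), which encodes proglucagon, the precursor of glucagon, GLP-1 and GLP-2, was at 16.6 ± 1.36 CPM in WT and 14.3 ± 1.75 CPM in HTZ crypts. The log2 fold change of -0.21 (SE 0.13) did not pass the test (edgeR, adjusted p = 0.357). The related factor Hnf1b had a log2 fold change of -0.16 (edgeR, adjusted p = 0.362). The enteroendocrine granule protein gene Chga was at 102 ± 8.64 and 102 ± 15.8 CPM (0.01; edgeR, adjusted p = 0.981). Neurog3, the factor that specifies enteroendocrine progenitors, had a log2 fold change of -0.20 (edgeR, adjusted p = 0.616). Among 20 genes for enteroendocrine hormones and granule proteins, 0 rose and 0 fell, and the list was not called (median 0.04, limma camera adjusted p = 0.982). Its most abundant gene, Chgb, had a log2 fold change of -0.14 and the gene for secretin, Sct, one of 0.32, and neither passed. Of 19 enteroendocrine transcription factors 18 had values below 0, with a median of -0.20 (camera adjusted p = 0.0592). The list was called down at a minimum of 50 counts and with the intron-share term in place of sex or beside it (camera adjusted p = 0.0389, 0.0431 and 0.0315). The member with the smallest p, Rfx3, was at -0.33 and did not pass. Of 13 L-cell and glucagon lineage genes 1 rose, the glucose transporter gene Slc5a1, which enterocytes also express, and the list was not called (median 0.31, camera adjusted p = 0.336).

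**Figure D1:**
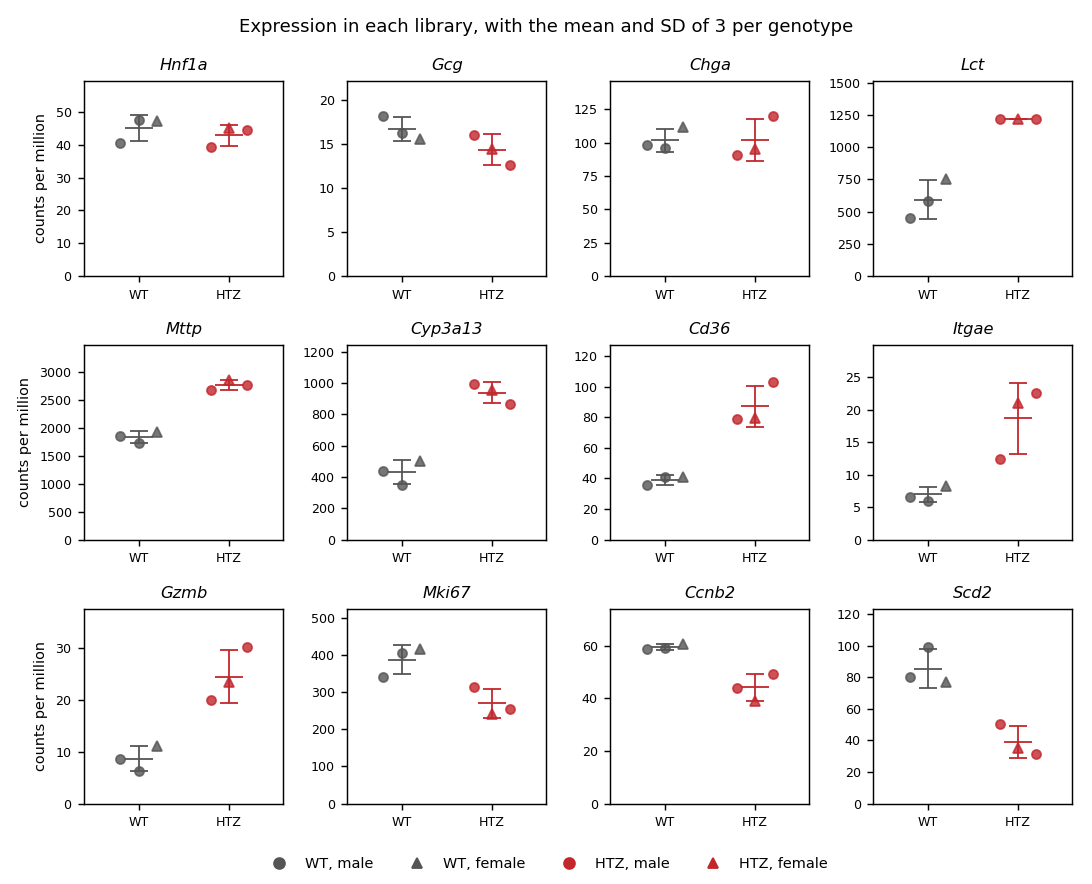
CPM in each library (y axis, from 0) for 12 genes in WT (grey) and HTZ (red) crypts, with circles for males and triangles for females. Bars give the mean and SD of 3 libraries per genotype. Hnf1a, Gcg and Chga overlap between genotypes, Lct, Mttp, Cyp3a13, Cd36, Itgae and Gzmb lie higher in all 3 HTZ libraries, and Mki67, Ccnb2 and Scd2 lie lower in all 3.

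The main comparison, of all crypt transcripts between the genotypes, showed changes that were mostly increases. In HTZ crypts 530 genes were higher and 25 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05). For 548 of these 555 genes the 3 HTZ libraries all lay on one side of the 3 WT libraries. Over all tested genes 29.3% did so, against 10% by chance. The median size of a change was 0.61 on the log2 scale, and 103 genes changed by more than 1. Among genes named by the rule fixed in advance, whose 3 HTZ libraries all lay above the 3 WT libraries, the largest rise was in Mcoln3, an endolysosomal cation channel, from 0.376 ± 0.0866 to 1.94 ± 0.916 CPM (log2 fold change 2.32, SE 0.43). Cubn, the receptor for intrinsic factor and vitamin B12, rose from 26.3 ± 22.5 to 96.2 ± 49.3 CPM (2.08, SE 0.31). The other 8 of the 10 largest rises were Tcrg-V7 (1.80) and Tcrg-C2 (1.62), segments of the T cell receptor gamma locus, the lymphoid transcription factor Ikzf1 (1.79), the leukocyte integrins Itgal (1.73) and Itgax (1.61), and Nckap1l (1.66), Cyfip2 (1.59) and Spn (1.57). Nckap1l and Cyfip2 belong to complexes that drive actin assembly, and Spn encodes a leukocyte surface sialoprotein. Except for Cubn, each of these 10 genes was below 10 CPM in both genotypes. The largest falls were smaller and were in genes of higher abundance. Scd2, a fatty acid desaturase, fell from 85.5 ± 12.2 to 39.1 ± 10.1 CPM (-1.13, SE 0.19) and cyclin D1 (Ccnd1) from 102 ± 7.53 to 70.4 ± 9.13 CPM (-0.53, SE 0.11). The serine synthesis enzyme Psat1 fell by 0.67, the Polycomb component Cbx6 by 0.56, Prelp by 0.50 and the glycine cleavage gene Gcsh by 0.49. The sterol synthesis enzyme Sqle fell by 0.48, and the centriole and spindle genes Sass6 and Kif22 fell by 0.47 and 0.46. Erdr1 also fell (by 0.71), but it lies on the sex chromosomes in a repeated region and its reads are uncertain.

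Leaving out WT male 2 left 0 edgeR calls (1993 genes at an unadjusted p under 0.05, 433 calls by DESeq2), WT male 1 left 1 (845 by DESeq2), HTZ male 2 left 90 and HTZ male 1 left 334, so that no gene described here kept its edgeR call in the model with sex without WT male 1 or WT male 2. Of the 555 genes, DESeq2 called 497 without WT male 1 and 377 without WT male 2 in the same direction, and edgeR without a sex term called 128 and 16. With a sex term, leaving out either female leaves the other fitted exactly. Both settings therefore amount to the males alone (826 genes), among which genotype coincides with intron share, and are given as such below. DESeq2 on all 6 libraries called 1517 genes (1167 higher, 350 lower) and no low-count filter gave 942 (738 and 204), while the 3 libraries of lower intron share alone gave 35 (29 and 6) and those of higher intron share 1204 (859 and 345), each with genotype and sex mixed as above.

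Genes of absorptive enterocytes, the cells that take up nutrients on the villus, were higher in HTZ crypts as a group. Of 42 such genes, all of them at 1 CPM or more in WT crypts, 27 rose and 0 fell (38 rose when adjusted over the list alone), with a median log2 fold change of 0.70. The brush border metalloprotease gene Mep1b rose from 392 ± 50.1 to 648 ± 6.04 CPM (0.73) and lactase (Lct) from 594 ± 155 to 1222 ± 2.19 CPM (1.07). Sucrase-isomaltase (Sis), the most abundant of the list, rose from 2594 ± 709 to 4045 ± 458 CPM (0.67), and Clec2h by 0.72. The list as a whole was called up (limma camera with a preset correlation, adjusted p = 1.09e-25), but not when the correlation between its genes was estimated (adjusted p = 0.314 with an estimated correlation). None of the 24 list calls held with an estimated correlation, and that p is given beside each. The calls of lipid absorption, xenobiotic metabolism and HNF1A targets were the 3 that held by fry, which tests a list's own direction. The enterocyte median was 0.40 within the libraries of lower intron share and 0.86 within those of higher intron share. Lymphocyte markers, described further on, moved in the same direction, and the lists of dividing and stem cells in the opposite one.

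Genes for fat uptake and chylomicron assembly, 12 of which are also in the enterocyte list, were higher as well. Of 28, 16 rose and 0 fell (22 adjusted over the list alone). The list median was 0.62 (camera adjusted p = 6.30e-18, adjusted p = 0.252 with an estimated correlation). Mttp, the transfer protein that loads lipid onto apolipoprotein B, rose from 1847 ± 104 to 2769 ± 87.3 CPM (0.59), and the fatty acid translocase Cd36 from 39.2 ± 3.11 to 87.1 ± 13.6 CPM (1.15, SE 0.12). The lipid-regulating transcription factor Creb3l3 rose from 174 ± 15.2 to 291 ± 9.81 CPM (0.74) and the lipid droplet protein gene Cideb by 0.59. Apoa4, the most abundant member, was at 2041 ± 1081 and 4539 ± 627 CPM (1.28), which did not pass (edgeR, adjusted p = 0.112). Of 29 PPAR-alpha and fatty acid oxidation genes 6 rose and 0 fell (11 adjusted over the list alone). Together they had a median of 0.25 (camera adjusted p = 4.15e-07, adjusted p = 0.384 with an estimated correlation). The peroxisomal oxidase Acox1 was among the genes that rose (0.56). Within the lower and higher intron share the medians were 0.43 and 0.78 for fat uptake and 0.35 and 0.19 for PPAR-alpha genes.

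Sugar handling and HNF1A target lists followed. Of 19 genes of glucose transport and fructose metabolism, 9 rose and 0 fell (11 rose and 1 fell adjusted over the list alone). The list median was 0.57 (camera adjusted p = 6.59e-07, adjusted p = 0.314 with an estimated correlation). Examples were the basolateral glucose transporter Slc2a2 (341 ± 86.8 to 607 ± 49.9 CPM, 0.86), ketohexokinase Khk (0.47), maltase-glucoamylase Mgam (0.57) and the sodium-glucose cotransporter Slc5a1 (1294 ± 385 to 2257 ± 504 CPM, 0.83). Of 33 HNF1A target genes taken from general knowledge of liver, kidney, islet and gut, 13 rose and 0 fell (19 adjusted over the list alone). Together they had a median of 0.54 (camera adjusted p = 3.83e-08, adjusted p = 0.252 with an estimated correlation). Cyp2j6 (0.76), Ugt2b5 (0.76) and the scaffold gene Pdzk1 (1.07) had the smallest p-values. Enterocyte genes made up 9 of these; of the other 24, 5 rose, 17 had positive values and the median was 0.35. Medians within the lower and higher intron share were 0.22 and 0.60 for sugar handling and 0.32 and 0.65 for HNF1A targets.

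Genes of xenobiotic and retinol metabolism formed a further raised group. Of 30, 9 rose and 0 fell (19 adjusted over the list alone). The list median was 0.66 (camera adjusted p = 3.09e-13, adjusted p = 0.252 with an estimated correlation). The medians within lower and higher intron share were 0.55 and 0.77. Retinal dehydrogenase Aldh1a1 rose from 465 ± 8.74 to 839.8 ± 72.7 CPM (0.85) and the retinol-binding protein gene Rbp2 from 1060.1 ± 177 to 1624 ± 17.9 CPM (0.62). The cytochrome P450 genes rose as well, Cyp3a13 from 431 ± 75.4 to 937 ± 66.5 CPM (1.13, SE 0.12) and Cyp2b10 from 137 ± 18.6 to 321 ± 40.2 CPM (1.23, SE 0.13). Of 23 iron and calcium absorption genes 1 rose, the ferroxidase Heph (0.55). Their median was 0.29 (camera adjusted p = 0.0149, adjusted p = 0.565 with an estimated correlation), or 0.03 and 0.35 within the split, and the call was lost without WT male 2 or HTZ male 2 and with the intron-share term in place of sex (adjusted p = 0.0976, 0.319 and 0.0612). Of 11 distal-intestine identity genes 2 rose, Cubn and the bile acid transporter subunit Slc51a (0.57). Their median was 0.57 (camera adjusted p = 0.0165, adjusted p = 0.314 with an estimated correlation), or -0.10 and 0.64 within the split, and the call was lost with the males alone (adjusted p = 0.0782). For 12 proximal identity genes the median was 0.14 and the list was not called (camera adjusted p = 0.144; 1 rose, Lct). It was called up without HTZ male 1 (adjusted p = 0.0367), was near the threshold with the males alone (adjusted p = 0.0512, or 0.0463 and 0.0482 with 1 female kept) and its direction turned without HTZ male 2 (adjusted p = 1).

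**Figure D2:**
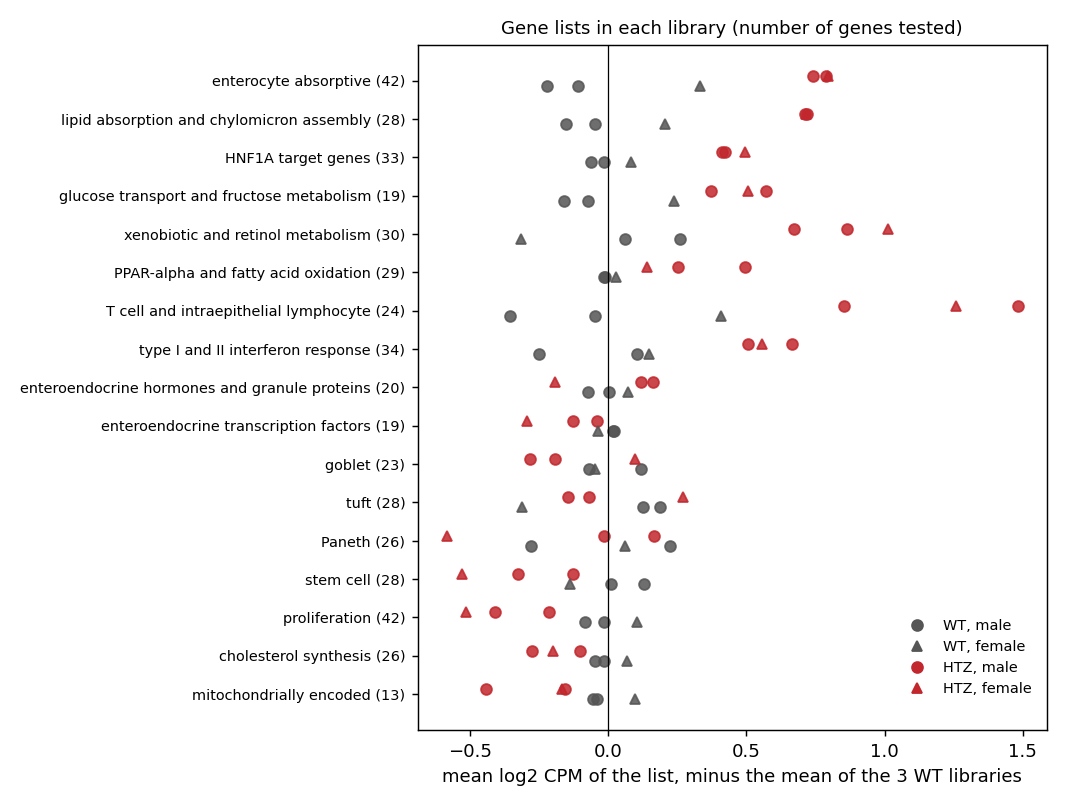
Mean log2 CPM of 17 gene lists in each library, as the difference from the mean of the 3 WT libraries (x axis), with WT in grey, HTZ in red, circles for males and triangles for females; the number of genes tested is in parentheses. The 3 HTZ libraries lie to the right of all 3 WT libraries for the enterocyte, lipid absorption, HNF1A target and lymphocyte lists and to the left for proliferation, while hormone, tuft and goblet lists overlap.

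Lists of dividing and stem cells were called down. All 42 proliferation genes had values below 0, of which 3 fell over all genes tested and 38 when adjusted over the list alone. The list had a median of -0.38 (camera adjusted p = 8.56e-17, adjusted p = 0.393 with an estimated correlation). Cyclin B2 (Ccnb2) fell from 59.5 ± 1.00 to 44.1 ± 5.17 CPM (-0.44), and survivin (Birc5) and the centromere histone Cenpa both fell by 0.38. Mki67 was at 387 ± 39.8 and 269 ± 38.3 CPM (-0.53), which did not pass (edgeR, adjusted p = 0.0602). All 28 stem cell genes also had values below 0, but none passed over all genes (10 fell adjusted over the list alone). Together they had a median of -0.35 (camera adjusted p = 4.20e-09, adjusted p = 0.314 with an estimated correlation). The smallest p-values were those of Slc14a1 (-0.56), Rgmb (-0.35) and Prom1 (-0.26), and the most abundant member, Olfm4, was at -0.41. Medians within the lower and higher intron share were -0.41 and -0.46 for proliferation but -0.02 and -0.53 for stem cell genes. Of 27 Wnt pathway genes 1 rose, Sp5 (0.68), and 1 fell, Ccnd1. Their median was -0.26 (camera adjusted p = 0.0024, adjusted p = 0.393 with an estimated correlation), or 0.02 and -0.44 within the split. The stem cell receptor Lgr5 had a log2 fold change of -0.57 and the most abundant, Fzd5, one of -0.03, and neither passed.

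The Paneth, goblet and tuft lists were not called, but each was called under some alternatives. The 26 Paneth genes had a median of -0.24 (camera adjusted p = 0.0547), with the most abundant, Lyz1, at 0.05 and Guca2b, which villus cells also express, at 0.89. The 23 goblet genes had a median of -0.11 (camera adjusted p = 0.0545), with Ccl9 at -0.41 and the most abundant, Fcgbp, at -0.09. None of these 4 genes passed. The 28 tuft genes had a median of -0.03, a mean of 0.02 and an upward direction (camera adjusted p = 0.982). Their mean level was lower in each library of lower intron share than in each of higher intron share. The Paneth list was called down without HTZ male 1 or WT male 2, by ranks and with the intron-share term in place of sex or beside it (camera adjusted p = 0.00731, 6.35e-07, 0.0441, 0.00424 and 0.00165), and turned upward, uncalled, with the males alone (0.798). The goblet list was called down with the males alone or without WT male 2 (camera adjusted p = 2.85e-04 and 0.0212). The tuft list was called down with the males alone (camera adjusted p = 4.55e-05) and up with the intron-share term in place of sex or beside it (0.0194 and 0.0203).

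Markers of immune cells were higher. Of 24 T cell and intraepithelial lymphocyte genes, 17 of them at 1 CPM or more in WT crypts, 9 rose and 0 fell (21 adjusted over the list alone), with the largest median of the called lists, 1.30. The list was called up (camera adjusted p = 4.28e-14, adjusted p = 0.384 with an estimated correlation), and its medians within lower and higher intron share were 0.85 and 1.46. The pan-leukocyte gene Ptprc rose from 12.8 ± 0.512 to 25.5 ± 3.94 CPM (0.98), the integrin Itgae of intraepithelial lymphocytes from 6.95 ± 1.21 to 18.6 ± 5.40 CPM (1.43), and granzyme B (Gzmb) from 8.63 ± 2.36 to 24.4 ± 5.17 CPM (1.53). Gzma, the most abundant member, was at 28.4 ± 10.3 and 68.8 ± 12.6 CPM (1.28) and did not pass (edgeR, adjusted p = 0.0914). Of 12 macrophage, dendritic cell and granulocyte genes 1 rose, Itgax. Their median was 0.72 (camera adjusted p = 0.0112, adjusted p = 0.314 with an estimated correlation), or 0.27 and 0.96 within the split, and the call was lost with the males alone (adjusted p = 0.0545). The 10 MHC class II genes had positive values, of which none passed. Their mean log2 CPM was 4.15, 2.95 and 1.98 in HTZ male 1, HTZ male 2 and HTZ female 2. In WT male 1, WT male 2 and WT female 1 it was 2.39, 1.51 and 2.71, so the genotypes overlapped. By this mean, these genes were higher in each library of lower intron share than in each of higher intron share. Their median was 1.06 (camera adjusted p = 0.0215, adjusted p = 0.644 with an estimated correlation), or 0.60 and 0.06 within the split, and the call was lost without HTZ male 1 or WT male 2 and with the intron-share term in place of sex or beside it (adjusted p = 0.321, 0.217, 0.116 and 0.0945). The 16 B cell and plasma cell genes were not called (median 1.12, camera adjusted p = 0.0589), and their median was 1.73 within the lower and -0.80 within the higher intron share. They were called up with the males alone, without HTZ male 2 and by ranks (camera adjusted p = 4.72e-07, 0.0455 and 0.0258).

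Interferon and epithelial defence genes moved in the same direction. Of 34 interferon response genes 9 rose and 0 fell (16 adjusted over the list alone). The list median was 0.65 (camera adjusted p = 6.21e-09, adjusted p = 0.393 with an estimated correlation), or 0.36 and 0.58 within the split. The genes that rose included Irf7 (27.7 ± 4.26 to 48.0 ± 5.23 CPM, 0.80), Oas3 (0.88), Rsad2 (1.22) and the most abundant, Ifi27l2b (0.59). Of 17 antimicrobial and inflammatory genes 3 rose and 0 fell (7 adjusted over the list alone). Together they had a median of 0.54 (camera adjusted p = 4.89e-04, adjusted p = 0.314 with an estimated correlation), or 0.43 and 0.63 within the split. Those that rose were the alarmin Il33 (6.07 ± 1.69 to 15.6 ± 3.93 CPM, 1.37), the C-type lectin Reg3a (80.3 ± 8.85 to 148 ± 17.7 CPM, 0.88) and Il18 (0.54). Of 10 type 2 response genes 2 rose, Il33 and the interleukin-13 receptor chain Il13ra1 (0.49). Their median was 0.38 (camera adjusted p = 0.0455, adjusted p = 0.475 with an estimated correlation; 0.44 within either side of the split), a call lost without WT male 1, with the males alone, by ranks and without a sex term (adjusted p = 0.108, 0.211, 0.0663 and 0.0532).

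Sterol and stress lists included calls in both directions. Of 26 cholesterol synthesis genes 1 fell, Sqle (64.4 ± 1.81 to 46.1 ± 4.97 CPM), and 0 rose (11 fell adjusted over the list alone). The list median was -0.19 (camera adjusted p = 7.15e-05, adjusted p = 0.496 with an estimated correlation), or -0.25 and -0.21 within the split. Cyp51 was at -0.47 (edgeR, adjusted p = 0.0508), Fdft1 at -0.40 and the most abundant, Stard4, at 0.03. Of 23 hypoxia and glycolysis genes 1 rose, the oxygen sensor Egln3 (0.80). Their median was 0.27 (camera adjusted p = 8.63e-04, adjusted p = 0.314 with an estimated correlation), or 0.0045 and 0.43 within the split. Of 22 immediate early genes 1 rose, Zfp36 (0.66). Their median was 0.39 (camera adjusted p = 0.00344, adjusted p = 0.514 with an estimated correlation), or 0.13 and 0.41 within the split. None of 16 heat shock genes passed. Their median was -0.40 (camera adjusted p = 0.00442, adjusted p = 0.644 with an estimated correlation), or -0.61 and -0.30 within the split, and the call was lost with the males alone or without WT male 2 (adjusted p = 0.134 and 0.202). Of 27 genes of the unfolded protein and integrated stress responses 1 fell, Psat1. The median was -0.22 (camera adjusted p = 0.049, adjusted p = 0.527 with an estimated correlation), or -0.30 and 0.01 within the split, and this call was lost in 11 of 16 alternatives, among them the males alone, without WT male 2 and without HTZ male 2 (adjusted p = 0.134, 0.0727 and 0.155). None of 70 nuclear oxidative phosphorylation genes passed. The median of 0.08 was called up (camera adjusted p = 0.00344, adjusted p = 0.565 with an estimated correlation; -0.04 and 0.18 within the split), a call lost without WT male 1 (adjusted p = 0.117).

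The remaining lists, called neither way, covered signalling and other tissues, and the camera adjusted p follows each median in parentheses. Medians were 0.12 (0.074) for 24 p53 and apoptosis genes, of which Casp3 (0.76) and Cdkn1a (0.59) rose, and 0.24 (0.157) for 14 regeneration genes, of which Il33 rose. They were 0.18 (0.27) for 15 glucocorticoid response genes, of which 2 rose, 0.35 (0.329) for 19 circadian clock genes and 0.02 (0.968) for 18 receptors and growth factors of the GLP and GIP axis. For 18 Notch genes the median was -0.02, the mean 0.08 and the direction down (0.648), and Dtx1 rose by 1.26. For 12 BMP genes the median was 0.03 (0.755), and Smad7 rose by 0.47. The glucocorticoid list was called up with the males alone and the clock list without HTZ male 2 (camera adjusted p = 0.0314 and 0.049), and p53 and apoptosis genes were called up, at the threshold, with a minimum of 50 counts (camera adjusted p = 0.04995). The median was -0.07 (0.136) for 29 secretory translocation genes. Lists of other cell types gave medians of 0.03 (0.997, direction down) for 8 microfold cell genes, 0.18 (0.997) for 9 Brunner gland and gastric genes and 0.24 (0.645) for 5 smooth muscle genes. They were -0.12 (0.906), with a mean of 0.02, for 8 endothelial genes, -0.11 (0.674) for 8 enteric neuron and glia genes and -0.04 (0.997) for 7 pancreatic genes.

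The share of counts from some abundant classes was lower in HTZ libraries. Mitochondrially encoded genes took 11.3 ± 0.304% of counts in WT and 9.15 ± 0.971% in HTZ (n = 3 each), ribosomal protein genes 3.14 ± 0.162% and 2.59 ± 0.159%. The 10 largest genes took 9.95 ± 0.884% in HTZ, a difference of -2.04 percentage points from WT. Most of the 10 genes with the largest mean share were mitochondrially encoded, so this difference overlaps with the mitochondrial one. Each of these differences had a two-sided exact permutation p = 0.1, the smallest that the 20 assignments of 3 libraries against 3 allow (adjusted p = 0.2 over 6 measures). Of 13 mitochondrially encoded genes 0 fell over all genes tested and 2 adjusted over the list alone. Their median was -0.27 (camera adjusted p = 9.21e-04, adjusted p = 0.571 with an estimated correlation), or -0.43 and -0.12 within the split.

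Because a targeted allele can carry flanking sequence of another strain, positions were examined too. Of 256 windows of 10 Mb, 1 held more changed genes than chance, on chromosome 6 from 40 to 50 Mb (10 of 61 tested genes, Fisher's exact test, adjusted p = 0.0357), and none did with windows of 5 Mb (smallest adjusted p = 0.488). Neither Hnf1a (chromosome 5) nor Gcg (chromosome 2) lies on that chromosome. Whether the 10 genes of the window belong to the raised lymphocyte and enterocyte groups was not tested, so the window is no sign of flanking sequence by itself. Of 234 tested genes within 10 Mb of Hnf1a 9 rose and 0 fell, and of 67 genes within 10 Mb of Gcg 5 rose and 0 fell. The neighbours of Hnf1a had a median log2 fold change of -0.07 (limma camera adjusted p = 0.337), or -0.10 for the 100 genes within 5 Mb (limma camera adjusted p = 0.134). The neighbours of Gcg had a median of -0.04 (limma camera adjusted p = 0.642), or 0.09 and an upward direction for the 29 genes within 5 Mb, of which 3 rose (limma camera adjusted p = 0.337).

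Sex served as a check of the labels. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in both female libraries. Against a floor of 3 counts per library (at most 0.101 CPM in the females) they were at least 480-fold, 627-fold, 358-fold and 214-fold higher in males; the floor covers counting error only. Xist was at 947 and 941 CPM in the females and between 0.842 and 2.16 CPM in the males, on library totals. Over both genotypes 6 genes differed between the sexes (edgeR, adjusted p under 0.05), all of them on the sex chromosomes: Xist, Kdm6a (0.75), Eif2s3x (0.65) and Kdm5c (0.67) were higher in females and Uty and Kdm5d lower. Ddx3y and Eif2s3y were not among the 6, although both had 0 counts in the females, so the test missed clear sex differences. DESeq2 called 26, upper-quartile scaling 3 and no filter 12, and leaving out HTZ female 2, WT female 1 or HTZ male 2 gave 41, 12 and 3.

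The genotype difference of the females was set against that of the males with an interaction term, with 1 female per genotype. It passed for 38 genes, 5 with a higher and 33 with a lower value in females (edgeR, adjusted p under 0.05), and 12 of the 38 lay among the 214 tested genes of chromosome 17 between 30 and 40 Mb (Fisher's exact test, adjusted p = 6.54e-11), the region of the major histocompatibility complex. Btnl6, a butyrophilin-like gene (chromosome 17, 34507804 to 34517352), was at 111 and 116 CPM in the HTZ males and 10.6 and 9.20 CPM in the WT males. It was at 18.2 CPM in the HTZ female and 81.4 CPM in the WT female, a difference of effects of -5.68 (SE 0.20). Aim2, a sensor of cytosolic DNA on chromosome 1 (173350879 to 173466040), was at 16.7 and 21.3 CPM in the HTZ males, 2.22 and 2.13 CPM in the WT males, 1.99 CPM in the HTZ female and 19.8 CPM in the WT female (-6.44). Rps18 on chromosome 17 (33951999 to 33956001) was at 208 and 181 CPM, 11.3 and 8.80 CPM, 7.63 CPM and 205 CPM in the same order (-9.03), but it has near-identical copies elsewhere and its counts are uncertain. The inflammasome sensor Nlrp1b on chromosome 11 (71153102 to 71230733) had at most 0.06 CPM in the HTZ males and the WT female and at least 4.47 CPM in the others. The long noncoding RNA RP23-359B23.11 on chromosome 8 (85125872 to 85132289) was at 117 CPM in the HTZ female, at 6.36 and 6.73 CPM in the WT males and at most 1.73 CPM in the others (8.42, SE 0.26). The fitted difference for Nlrp1b, 17.5, rests on libraries near 0 counts and is no measure of size. For 30 of the 38 genes the libraries of lower and higher intron share did not overlap, against 10.6% of all tested genes. The interaction contrasts these same sets of libraries, so the higher share is no separate evidence for the division. Leaving out HTZ male 1, HTZ male 2, WT male 1 or WT male 2 gave 208, 145, 15 and 12 genes, DESeq2 141 and no low-count filter 186.

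**Figure D3:**
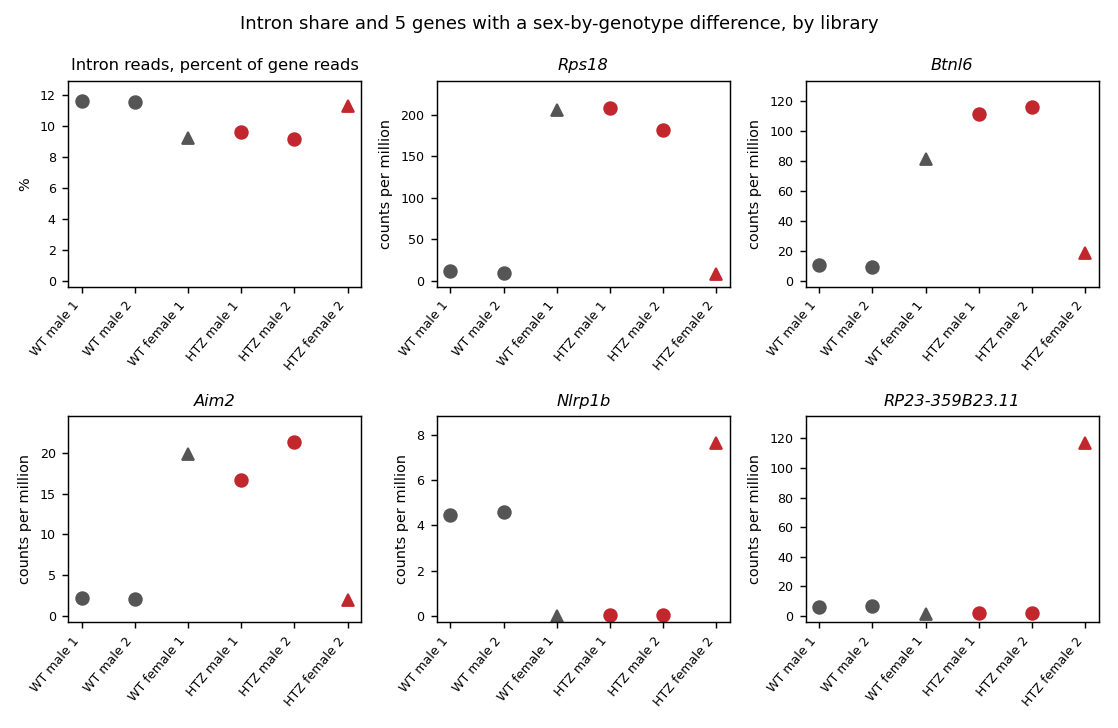
Percent of gene reads in introns (first panel) and CPM of 5 genes with a sex-by-genotype difference (other panels, y axes from 0) in each of the 6 libraries, WT in grey, HTZ in red, circles for males and triangles for females. WT female 1 lies with the HTZ males and HTZ female 2 with the WT males in the intron share, Rps18, Btnl6, Aim2 and Nlrp1b.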

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

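All tests of explanations in this part, and the use of intron share, were chosen after the result had been seen, while the comparison of the sexes was planned. The genotype difference of the females departed from that of the males for 38 genes by the interaction term (edgeR, adjusted p under 0.05), and each of the 5 with the smallest p is given as the effect in females minus that in males on the log2 scale. These were 8.42 for RP23-359B23.11, -9.03 for Rps18, -5.68 for Btnl6, -6.44 for Aim2 and 17.5 for Nlrp1b. The last is a fitted value on libraries near 0 counts and gives no size, and Rps18 has near-identical copies. The count was 15 without WT male 1, 12 without WT male 2, 208 without HTZ male 1 and 145 without HTZ male 2, and neither female could be left out.

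In many of these genes WT female 1 lay with the HTZ males and HTZ female 2 with the WT males, the division that intron share also gave. It separated 30 of the 38 genes, where all tested genes gave 10.6%. The interaction contrasts the same sets of libraries, so genes chosen by it tend to be separated in this way. The higher share is therefore no separate evidence for the division. Sequence differences between mouse strains among the animals may account for part of the pattern, since 12 of the 38 genes lay in 1 window of chromosome 17 (Fisher's exact test, adjusted p = 6.54e-11); the other 26 genes lay elsewhere. An exchange of the labels of the 2 female libraries would make the exchanged split the real one, and the counts ran against it, with 8 genes called by that split and 555 by the labelled one, but it was not excluded, since the 555 could follow a difference in preparation and the exchanged split is also the division by intron share. The HTZ female's number differs between its title and the name of its deposited table, while both give its genotype as HTZ. An effect of genotype that differs between the sexes stays open too, as there was 1 female per genotype. Apart from the division, WT female 1 lay between the WT males and the HTZ libraries in the enterocyte list. Its mean log2 CPM there was 9.15, against 8.71 and 8.59 in WT male 1 and WT male 2. HTZ male 1, HTZ male 2 and HTZ female 2 were at 9.60, 9.56 and 9.61. Whether this adds to the interaction genes was not tested.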

How the results depend on the processing

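Chosen after the data were seen were unique exon reads, the terms for the division by intron share and each side of it alone, leave-one-out without a sex term or with DESeq2, and removal of list genes. Against 555 genes changed by genotype there were 942 with no low-count filter, 1517 with DESeq2 (552 of the 555 in the same direction), 350 with a non-robust fit, 35 in the 3 libraries of lower intron share alone and 1204 in those of higher intron share alone, where genotype is mixed with sex and 1 genotype has 1 library. Leaving out 1 library gave 0 (without WT male 2, edgeR, with 1993 genes at an unadjusted p under 0.05 and 433 by DESeq2) to 1188 (without HTZ male 1, DESeq2). Apart from the replicate block, the other 12 alternatives with all libraries or males only gave 382 (upper-quartile factors, 372 shared) to 826. More genes were higher than lower in each of these settings that called any gene. The cause was not tested. With a sex term, leaving out either female amounts to the males alone, where genotype coincides with the division by intron share.

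With male 1, male 2 and the females, whose numbers differ, each paired across genotypes as a replicate block, 352 genes changed, 320 of them shared with the 555, and Chga was at -0.0034. The block called the Paneth and goblet lists down and the B cell list up (camera adjusted p = 0.0162, 0.0354 and 0.0324), which were not called in the model with sex on all 6 libraries. Nothing in the labels says that the numbers pair the libraries, and deviations from the genotype means correlated by 0.0669, -0.114 and -0.0580 in the male 1, male 2 and female pairs.

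Genes differing between the sexes were 6, against 12 with no filter, 3 with upper-quartile factors, 26 with DESeq2 and 3 to 41 with 1 library left out. The sex-by-genotype genes were 38, against 186 with no filter, 141 with DESeq2 and 12 to 208 with 1 male left out. Of 24 called lists 0 were called with an estimated correlation and 3 by fry, and the other alternatives gave 22 to 27. The 1 window of changed genes became 0 with windows of 5 Mb and 0 for genes at an unadjusted p under 0.01. The cause was not tested. Hnf1a (-0.14 to -0.01) and Gcg (-0.32 to -0.10) stayed below 0 and uncalled under each alternative run. The lower share of mitochondrially encoded genes kept its direction but was -0.37 percentage points without the 10 largest genes, against -2.17, since that setting removes genes of the same class.

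Reversals were seen in 6 genes that were not called. Chga (0.01) was at -0.020 with no filter, -0.0011 at 50 counts, -0.033 with upper-quartile factors, -0.0030 with limma-voom, -0.013 without mitochondrial genes and the 10 largest genes, and -0.053 with the intron-share term in place of sex. That term turned Lyz1 to -0.059, Fcgbp to 0.049 and Fzd5 to 0.040, males only turned Neurog3 to 0.076, and upper-quartile factors turned Stard4 to -0.0057. Leaving out 1 library gave -0.15 to 0.12 for Chga, -0.39 to 0.076 for Neurog3, -0.13 to 0.27 for Lyz1, -0.38 to 0.065 for Fcgbp, -0.077 to 0.11 for Stard4 and -0.16 to 0.049 for Fzd5. The cause was not tested. Of 63 named genes called by genotype, 46 were called with a non-robust fit, 44 with the replicate block, 21 without HTZ male 2, 41 without HTZ male 1 and 0 without WT male 1 or WT male 2. In simulated libraries of the same number, depth and spread 23.9% of changes of 0.5 were recovered, and how much of this depth sets was not tested. For genes at 0 counts in the females, depth sets a floor of at most 0.101 CPM (3 counts per library).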

Other observations

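All tests in this part were chosen after the results had been seen, except that the scaling alternatives used in it had been fixed beforehand. Among the other genes of the chromosome 17 window were the MHC class I genes H2-Q2, at 332, 361 and 219 CPM in HTZ male 1, HTZ male 2 and WT female 1 against 7.16, 4.71 and 8.36 CPM in WT male 1, WT male 2 and HTZ female 2, and H2-D1, at 309, 349 and 258 against 85.5, 69.2 and 107 CPM in the same order. Further genes of this family lie in the same window and resemble them, so their counts are uncertain, as for Rps18. Reads in introns, tested by genotype in the same way, called 0 of 12903 genes (edgeR; 1567 at an unadjusted p under 0.05). Of the 525 genes called by exon reads and tested by intron reads, 511 had the same direction in both (97.3%, against 72.0% of genes that were not called). The median intron change of the genes that rose was 0.48 and the median exon change 0.60.

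The pattern weighed was that enterocyte, lipid and lymphocyte lists were called up and proliferation and stem cell lists down. Unequal scaling from a few abundant genes was weighed by changing the scaling. Without mitochondrial genes and the 10 largest genes, 488 of 555 genes were still called in the same direction. With median-of-ratios factors 543 were, and with upper-quartile factors 372 (67.0%). The median log2 fold change over all genes, -0.01, became -0.03, -0.01 and -0.05 in these settings, so the scale itself changed little. Most calls thus did not hang on those abundant genes, while a scaling error shared by all these settings was not tested. Villus tissue carried over into the HTZ preparations may account for the pattern and would lower Paneth genes as far as proliferation genes, but the Paneth median lay 0.14 above that of proliferation with an SD of 0.31 between its members, which decides nothing. A shift of differentiation within the HTZ crypts cannot be told apart from it for the epithelial lists, as the median of the enteroendocrine transcription factors, -0.20, decides nothing either. With an unchanged share of lymphocytes, such a shift would not raise lymphocyte genes. Their 24 members all had positive values (median 1.30, SD 0.19), with each HTZ library above each WT library. The rise was part of the pattern weighed, so these values show only that a shift with an unchanged lymphocyte share leaves the rise unexplained. The 24 members varied together (estimated correlation 0.56) and are not 24 separate signs. Whether a shift could itself raise the number of lymphocytes was not tested. With 3 libraries against 3 the 10 splits are too few for a share under 0.05: 1 of 10 gave as many genes, the real one with 555, and the highest other gave 8.

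Some clock genes stood apart in both male 2 libraries. Dbp was at 3.22 and 2.14 CPM in WT male 2 and HTZ male 2 against 14.8 to 52.7 CPM in the others and Arntl at 49.8 and 57.3 against 18.0 to 32.4 CPM. These 2 were picked after their values were seen. Of 19 clock genes, 16 deviated to the same side in both libraries, and not all of these lay outside the range of the other libraries. A general batch shared by both libraries did not show, with a correlation of their deviations over all genes of -0.11, but it was not excluded. Each male 2 library was set against a mean that includes the female of the other side of intron share. For genes that follow that division, the deviations are thereby pushed in opposite directions. Another time of day at collection for both animals may be the cause, since over 19 clock genes the deviations correlated by 0.91, above 98.98% of 10000 random lists. This cannot be told apart from other causes, because the pattern drew attention to these genes, that share fell just short of the 99% set for the test, the male 1 and female pairs gave 0.51 and 0.72, and collection times are not given.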
